A study of Mus musculus with 20 samples.

How the data were processed

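RNA sequencing of differentiated 3T3-L1 cells was analysed in 20 libraries of 8 groups: overexpression and knockdown of Foxk1 (3 libraries per group) and of Foxk2 (2 per group), each with its own controls. Per the labels' protocols, differentiation used 1 µM dexamethasone, 0.5 mM IBMX, 5 µg/ml insulin and 10 µM troglitazone, with insulin only from day 4 and growth medium from day 6.

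The authors deposited 1 table of RPKM values (reads scaled to gene length and to the assigned reads of the library) for 48440 genes in 20 libraries. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 2.1.0, processed with Picard 1.141, counted with featureCounts of Subread 1.5.1 and turned into RPKM with edgeR. The strand of the libraries is not stated. 18295 genes are 0 in every library. GENCODE M21 gave symbols and coordinates: 40606 identifiers match it with their version and 48058 without. RPKM multiplied by the length of merged exons gave whole reads, within 0.1 read, for every value above 0 of identifiers matching with their version, so depth per library could be recovered: 16739763 to 20772823 reads in the Foxk1 groups and 31378224 to 36157008 in the Foxk2 groups. For 5813 genes of other versions, reads rest on the shortest length that makes them whole. Mitochondrial genes held 3.79 to 7.80% of reads.

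Values were taken as log2(RPKM + 0.5), which understates fold changes of genes near the pseudocount. Genes with an RPKM of 0.5 or more in at least 2 libraries were tested (15981). A linear model with 8 group means over all libraries was fitted in limma 3.58.1 (R 4.3.3) with a mean trend in the prior variance and 12 residual degrees of freedom. Each manipulation was compared with its own controls, two-sided, and a gene changed where the Benjamini-Hochberg adjusted p was under 0.05. Errors are the model's SE for fold changes and the SD between libraries for RPKM. The labels do not say that replicates are separate cultures, so p-values measure the spread between these libraries alone, which may be technical. The median SD of log2 values within a group was 0.0391 to 0.0819.

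Gene lists were written before the data were examined (40 lists, 844 genes) and tested with camera in limma where at least 3 members were measured (37 lists). The correlation between members was preset at 0.01, and each test was repeated with the correlation estimated per list. The adjusted p of a list is over the lists of that comparison. Differences between the effects of Foxk1 and Foxk2 were tested as contrasts of contrasts in the same model. Genes called in both of 2 comparisons were counted by direction, against the counts that independent lists of the same sizes would give.

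The genes named were set by a rule written before the data were examined: both targets; in each comparison the 8 rises and 8 falls of largest size among called genes with a mean of 2 RPKM or more in the higher group, ranges apart and no predicted or clone name; up to 4 members of smallest p from each called list, and always from the glycolysis, pyruvate dehydrogenase, adipocyte and fibroblast lists; and for each pair of comparisons 6 genes per direction class. Where 5 or fewer members of a list went one way, those outside the rule are named as well. They, Krt18, Acta1 and Des were chosen after their values were seen. Some genes that these rules would name are not reported here.

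In simulated data, 200 genes were changed 1.25 to 4 fold, in 10 draws per comparison. Of calls, 14.9 to 16.9% were false, above the nominal share, and 52.0 to 71.2% of these had a mean under 20 reads. With a filter at 20 reads, 7.55 to 9.89% were false, and with voom on whole reads 6.28 to 10.4%. The test recovered 68.4 to 79.7% of genes changed 2 fold and 30.2 to 49.4% of those changed 1.25 fold, so absence of a call does not show a lack of change. These shares need not hold for the data, where 5386 to 7643 genes were called.

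Alternatives set before the data were examined were 2 filters, 2 pseudocounts, 2 other scalings, 2 smaller models, a robust fit, voom on recovered reads, a replicate block, each library left out, and the estimated correlation. Added after the data were examined were removal of a trend on gene length and GC content, omission of mitochondrial genes, a filter at a mean of 20 reads, and the glycolysis list without members that near-identical copies cover. Such copies were searched among GENCODE M21 transcripts with BLAST+ 2.17.0 at 99% identity over 100 bases or more. Copies outside that annotation would be missed. Figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.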

Results

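3T3-L1 adipocytes, a mouse preadipocyte line differentiated into fat cells in culture, were compared with their own controls after overexpression or knockdown of Foxk1 or of Foxk2, paralogous forkhead transcription factors. The published study on these samples concerns glucose use, so glycolysis counts in any comparison are not independent evidence of their direction.

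The first principal component held 79.5% of the variance and parted the Foxk1 groups (-74.6 to -62.0) from the Foxk2 groups (98.6 to 102), controls included. Effects of the 2 factors set side by side thus cross sets of libraries that also differ in depth and replicate number. Control means of Gapdh, uncertain through near-identical copies, differ too (13.7 and 18.3 RPKM with Foxk1, 1.62 and 1.93 with Foxk2).

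Foxk1 (ENSMUSG00000056493.9, chromosome 5, 142401497 to 142462011 in mm10) fell in Foxk1 knockdown from 8.32 ± 0.424 to 3.25 ± 0.265 RPKM (SD, n = 3 and 3), a log2 fold change of -1.23 ± 0.055 (SE, adjusted p = 4.19e-10). It did not rise in the libraries labelled Foxk1 overexpression: it fell there from 7.55 ± 0.468 to 6.10 ± 0.0553 RPKM (SD, n = 3 and 3; -0.28 ± 0.055, adjusted p = 0.000515). Foxk2 (ENSMUSG00000039275.9, chromosome 11, 121259990 to 121309896) rose in Foxk2 overexpression from 13.4 ± 0.123 to 19.96 ± 0.0356 RPKM (SD, n = 2 and 2; 0.56 ± 0.049, adjusted p = 1.95e-07). Foxk2 knockdown lowered it from 12.9 ± 0.282 to 3.27 ± 0.0271 RPKM (SD, n = 2 and 2; -1.83 ± 0.049, adjusted p = 6.75e-12). The paralogue moved in each comparison as well: Foxk2 by 0.29 ± 0.040 in the labelled Foxk1 overexpression and -0.19 ± 0.040 in Foxk1 knockdown, Foxk1 by -0.66 ± 0.067 in Foxk2 overexpression and 0.30 ± 0.067 in Foxk2 knockdown. The call of Foxk1 in Foxk2 knockdown was lost with a length and GC trend removed (0.062, adjusted p = 0.416), and that of Foxk2 in Foxk1 knockdown in a model of that comparison alone (adjusted p = 0.0557). Whether Foxk1 protein or a construct transcript was higher in the labelled libraries is not shown by these values, so every direction below for them is that of the label.

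**Figure D1:**
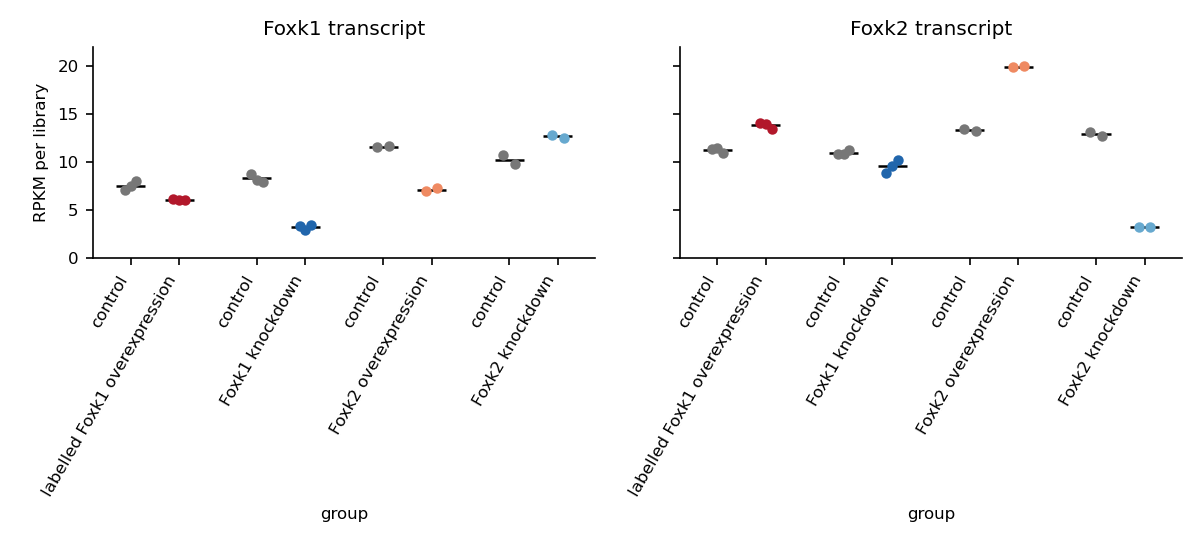
RPKM of Foxk1 and Foxk2 in each library (points) with the group mean (line), for each manipulation beside its own controls.

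In the libraries labelled Foxk1 overexpression, Cidea, Elovl3 and Adm2 were among the most raised genes and Clec3b, Ogn and Itgbl1 among the most lowered, relative to the controls of that label. Cidea, which coats lipid droplets, rose from 3.46 ± 0.414 to 31.5 ± 1.05 RPKM (SD, n = 3 and 3; log2 fold change 3.02 ± 0.11 SE, adjusted p = 1.08e-11; ENSMUSG00000024526.8, chromosome 18, 67343604 to 67367785). Elovl3, a fatty acid elongase, rose by 2.73 ± 0.11 and the calcium pump gene Atp2a3 by 2.07 ± 0.071. Clec3b, which encodes the plasminogen-binding protein tetranectin, fell from 60.5 ± 5.09 to 3.31 ± 0.184 RPKM (-4.00 ± 0.069, adjusted p = 3.08e-15; ENSMUSG00000025784.4, chromosome 9, 123150946 to 123157432).

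Of 15981 genes tested, 7643 changed, 3847 upward and 3796 downward, and 168 rose and 410 fell at least 2-fold. Ranges of the 2 groups did not overlap for 52.3% of genes tested, against 10.0% by chance. Further large rises were in Adm2, a secreted peptide gene (2.48), Gfra1, a receptor subunit (2.34), Aspg, an asparaginase (2.24), mitochondrial Chchd10 (2.18) and Ddit4, an inhibitor of growth signalling (2.11). The matrix gene Ogn (-3.88), Itgbl1 (-3.48), the growth factor gene Ptn (-3.45), the peptidase inhibitor gene Pi15 (-3.40) and the scavenger receptor gene Scara3 (-2.96) fell. The short microRNA gene Mir126b had 3 to 8 reads per control library and is listed at 0 in the labelled ones, so no fold is given.

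Glycolysis enzymes had a median of 1.01, with 13 higher, 2 lower and 2 not passing (adjusted p = 1.12e-06, or 0.142 with an estimated correlation). Of 22 hypoxia and HIF1 targets, 20 rose, 1 fell and 1 did not pass (median 0.60, adjusted p = 1.52e-09, or 0.0897 with an estimated correlation). The median of glucose and lactate transport genes was 0.53, from 4 higher, 0 lower and 3 not passing (adjusted p = 0.0131, or 0.251 with an estimated correlation). Among pentose phosphate pathway genes, 6 rose, 1 fell and 1 did not pass, with a median of 0.36 (adjusted p = 0.00835, or 0.232 with an estimated correlation). Thermogenic and brown fat genes had a median of 0.65, with 6 higher, 1 lower and 2 not passing (adjusted p = 0.0121, or 0.142 with an estimated correlation). Of 54 nuclear-encoded respiratory chain genes, 46 rose, 0 fell and 8 did not pass (median 0.24, adjusted p = 9.11e-13, or 0.142 with an estimated correlation). The median of TCA cycle genes was 0.19, from 16 higher, 2 lower and 3 not passing (adjusted p = 4.07e-05, or 0.230 with an estimated correlation). Gapdh (1.29), Hk2 (1.04), Pgam1 (1.19) and Eno1 (1.01) rose in glycolysis. The glucose carrier genes Slc2a1 (0.90) and Slc2a4 (0.53), the lactate carrier gene Slc16a1 (0.79) and Slc16a3 rose. So did the pyruvate dehydrogenase kinase gene Pdk1 (1.16), Tkt (0.87) and Idh3a (0.94). Against the rest of their list fell Eno3 and Ldhb (glycolysis enzymes), Adm (hypoxia and HIF1 targets), H6pd (pentose phosphate pathway) and Adrb3 (thermogenic and brown fat). To these add Idh1 and Idh2 (TCA cycle).

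Reads of 3 glycolysis genes may be shared with near-identical copies, since 88.0% of the Gapdh transcript, 85.6% of Eno1 and 68.8% of Pgk1 match other genes, so their levels are uncertain. Without these 3 the glycolysis list gave, in the labelled Foxk1 overexpression, median 0.88, adjusted p = 9.59e-05, or 0.198 with an estimated correlation. In the same order, Foxk1 knockdown gave median -0.74, adjusted p = 2.89e-07, or 0.0581. Foxk2 overexpression gave median 0.83, adjusted p = 4.07e-05, or 0.193. Foxk2 knockdown gave median -0.23, adjusted p = 0.0338, or 0.375.

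**Figure D2:**
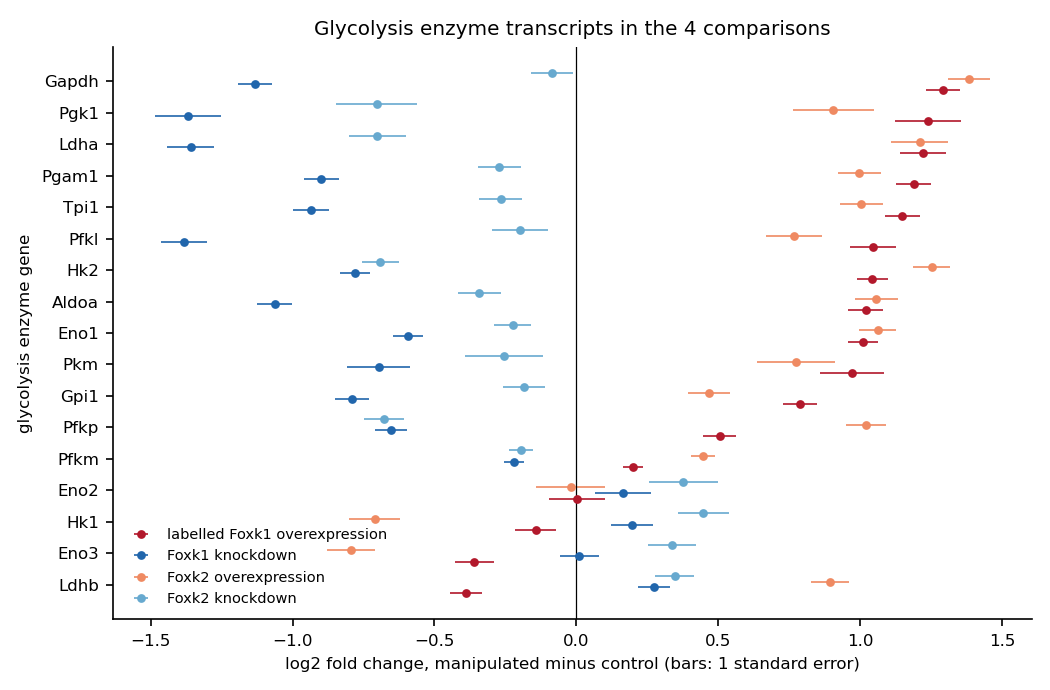
Log2 fold change of each glycolysis enzyme transcript against its own controls (points, bars 1 SE) in the 4 comparisons. In the libraries labelled Foxk1 overexpression 13 of 17 rose and in Foxk1 knockdown 13 fell; Gapdh, Eno1 and Pgk1 may share reads with near-identical copies.

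Among fibroblast and preadipocyte markers, 0 rose, 20 fell and 2 did not pass, with a median of -1.16 (adjusted p = 4.18e-15, or 0.0897 with an estimated correlation). Extracellular matrix genes had a median of -0.71, with 1 higher, 30 lower and 3 not passing (adjusted p = 6.90e-18, or 0.0897 with an estimated correlation). Of 13 myofibroblast and contractile genes, 2 rose, 9 fell and 2 did not pass (median -0.53, adjusted p = 0.00125, or 0.218 with an estimated correlation). The median of Wnt pathway genes was -0.47, from 1 higher, 15 lower and 2 not passing (adjusted p = 4.46e-06, or 0.137 with an estimated correlation). Among adipocyte markers, 5 rose, 12 fell and 4 did not pass, with a median of -0.24 (adjusted p = 0.00835, or 0.20 with an estimated correlation). NF-kB and inflammatory cytokine genes had a median of -0.15, with 2 higher, 8 lower and 8 not passing (adjusted p = 0.0489, or 0.142 with an estimated correlation). Of 30 lysosome genes, 7 rose, 21 fell and 2 did not pass (median -0.25, adjusted p = 0.00108, or 0.142 with an estimated correlation). The fibroblast receptor gene Pdgfra (-2.68), the collagen-binding Dcn (-2.73), Postn (-2.02) and Sparc (-1.05) fell, and so did the matrix protease gene Mmp2 (-2.26) and its inhibitor Timp2 (-2.15). Lox, Wnt5a and the chemokine gene Cxcl12 fell too (-1.26, -1.12 and -2.36). Among mature adipocyte products, Adipoq (-1.32), Cidec (-1.004), Cfd (-0.72) and the adrenergic receptor Adrb3 (-2.25) fell. Higher against the rest of their list were Lamc1 (extracellular matrix), Tgfb1 (myofibroblast and contractile), Fzd8 (Wnt pathway) and Adig, Cebpa, Cebpb, Fabp5 and Slc2a4 (adipocyte markers). To these add Lcn2 and Nfkbia (NF-kB and inflammatory cytokines).

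The median of cell cycle genes was 0.63, from 26 higher, 2 lower and 5 not passing (adjusted p = 8.48e-08, or 0.0897 with an estimated correlation). Among ribosomal proteins, 42 rose, 0 fell and 5 did not pass, with a median of 0.31 (adjusted p = 1.34e-13, or 0.0897 with an estimated correlation). MYC target and ribosome biogenesis genes had a median of 0.22, with 19 higher, 0 lower and 5 not passing (adjusted p = 4.46e-06, or 0.0804 with an estimated correlation). Of 30 ER stress and ATF4 targets, 20 rose, 5 fell and 5 did not pass (median 0.48, adjusted p = 1.10e-05, or 0.142 with an estimated correlation). The median of cholesterol synthesis genes was 0.32, from 16 higher, 1 lower and 5 not passing (adjusted p = 3.54e-06, or 0.233 with an estimated correlation). Among fatty acid and triglyceride synthesis genes, 10 rose, 2 fell and 6 did not pass, with a median of 0.17 (adjusted p = 0.0169, or 0.365 with an estimated correlation). Fatty acid oxidation genes had a median of 0.13, with 14 higher, 2 lower and 4 not passing (adjusted p = 0.00379, or 0.246 with an estimated correlation). Of 15 heat shock genes, 9 rose, 3 fell and 3 did not pass (median 0.17, adjusted p = 0.0334, or 0.142 with an estimated correlation). Plk1 (1.2) and Mki67 (0.83), which mark dividing cells, rose from under 1 RPKM, and the spermidine synthase gene Srm rose by 0.49 ± 0.053. Atf4 (0.71) and Ppp1r15a (1.12), of the stress response, and Dgat2 (1.11), which makes triglyceride, were higher, as were Sqle (0.93) and Elovl6 (1.48). Lower than controls, unlike most of their list, were E2f1 and Mcm4 (cell cycle), Calr, Dnajb9, Hsp90b1, Pdia4 and Phgdh (ER stress and ATF4 targets), Insig1 (cholesterol synthesis) and Scd1 and Srebf1 (fatty acid and triglyceride synthesis). To these add Cpt1a and Cpt2 (fatty acid oxidation) and Cryab, Hspa1a and Hspa1b (heat shock).

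With p-values adjusted over the list alone, 20 of 24 MYC target and ribosome biogenesis genes, 19 of 22 cholesterol synthesis genes, 32 of 34 extracellular matrix genes and 21 of 22 fibroblast and preadipocyte markers passed. So did 47 of 54 nuclear-encoded respiratory chain genes, 43 of 47 ribosomal proteins and 9 of 9 thermogenic genes (6 higher, 3 lower). Such counts pool directions (1 fibroblast marker rose). Other called lists kept theirs. No list kept its call here with an estimated correlation. Quantile normalization ended the calls of the NF-kB, heat shock, glucose transport, fatty acid synthesis and fatty acid oxidation lists, and a filter at a mean of 1 RPKM those of the heat shock and thermogenic lists. The NF-kB call was also lost with pseudocount 1, median-ratio scaling, each smaller model, the replicate block and the 20-read filter (heat shock too), and without control or labelled replicate 3, and the fatty acid synthesis call in a model of this comparison alone. Without control replicate 2 the p53, pyruvate dehydrogenase, histone and interferon lists passed too, as they did without a filter, and p53 without labelled replicate 1. Not called were FoxO target and insulin signalling genes (median -0.027, adjusted p = 0.727), Foxk family and Sin3 partner genes (median 0.080, adjusted p = 0.192) and NRF2 targets (median 0.072, adjusted p = 0.571). Nor were PFKFB and glycogen genes (median 0.19, adjusted p = 0.179), autophagy genes (median -0.029, adjusted p = 0.439) and circadian clock genes (median 0.15, adjusted p = 0.244). No call fell to gluconeogenesis and glyceroneogenesis genes (median 0.17, adjusted p = 0.323), immediate early genes (median -0.14, adjusted p = 0.571) and interferon response genes (median -0.22, adjusted p = 0.0851). Nor were lipolysis and lipid droplet genes (median -0.046, adjusted p = 0.924), macrophage markers (median 0.16, adjusted p = 0.924) and mitochondrially encoded transcripts (median -0.0071, adjusted p = 0.572). No call fell to p53 targets (median 0.13, adjusted p = 0.0559), pyruvate dehydrogenase regulation genes (median 0.30, adjusted p = 0.0559) and replication-dependent histones (median -0.55, adjusted p = 0.0888). Median, mean and test differed in sign for lipolysis and lipid droplet genes (median -0.046, mean 0.27, tested higher) and macrophage markers (median 0.16, mean -0.10, tested higher).

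**Figure D3:**
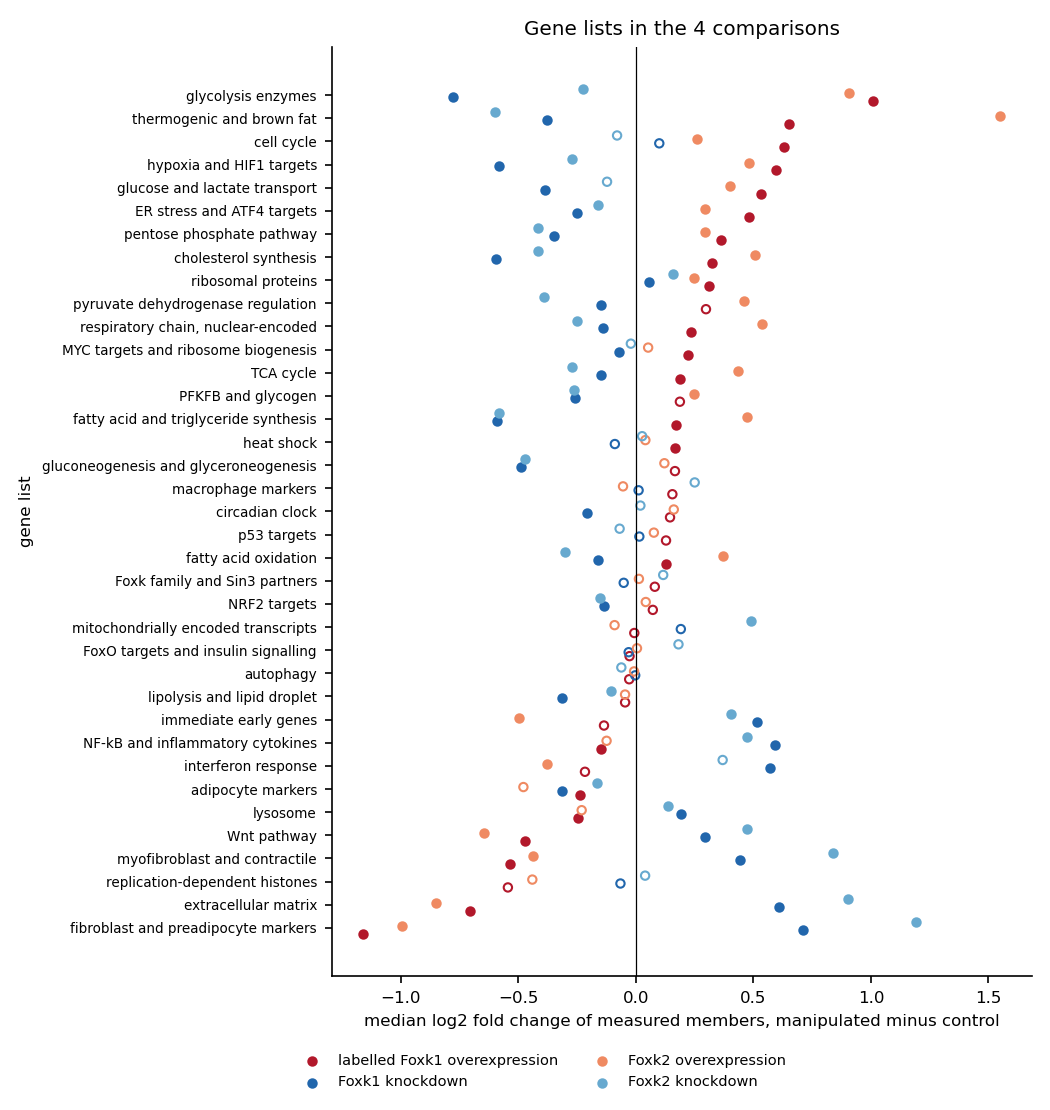
Median log2 fold change of the measured members of each gene list in the 4 comparisons, filled where the camera adjusted p passed with a preset correlation and open where it did not.

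In Foxk1 knockdown Egln3, Ero1l and Ak4 were among the most lowered genes and Thbs1, Grem1 and Ccl8 among the most raised. Egln3, an oxygen-sensing hydroxylase, fell from 42.6 ± 5.68 to 6.16 ± 0.810 RPKM (SD, n = 3 and 3; log2 fold change -2.69 ± 0.12 SE, adjusted p = 3.84e-10; ENSMUSG00000035105.5, chromosome 12, 54178981 to 54203860). Ero1l, which oxidises proteins in the endoplasmic reticulum, fell from 163 ± 9.55 to 35.6 ± 1.57 RPKM (-2.18 ± 0.11). Thbs1, a matrix glycoprotein gene, rose from 37.0 ± 3.12 to 138 ± 3.61 RPKM (1.89 ± 0.078, adjusted p = 2.25e-10; ENSMUSG00000040152.8, chromosome 2, 118111876 to 118127133).

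Among the 15981 genes, 3260 rose and 2474 fell (5734 in all), 168 and 95 of them at least 2-fold. With a length and GC trend removed from each library, the split was 2662 higher and 3524 lower, so 56.9% higher became 43.0%. Both other scalings reversed it too. Group ranges lay apart for 44.2% of genes tested (10.0% by chance). Grem1, an antagonist of bone morphogenetic proteins (2.17), the chemokine gene Ccl8 (1.95), the protease gene Mmp3 (1.86), Rgs16 (1.81) and the cytokine receptor gene Il2ra (1.76) rose. Apoa4, of lipoproteins (-3.23), Cyp2ab1 (-2.64), the adenylate kinase gene Ak4 (-2.44) and the cytochrome oxidase subunit gene Cox7a1 (-2.20) fell. Mir7025, Mir194-1, Mir7666 and Snord73a passed the test on at most 6 reads in a library, so their changes are uncertain and no fold is given.

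The median of glycolysis enzymes was -0.78, from 2 higher, 13 lower and 2 not passing (adjusted p = 4.77e-10). Among hypoxia and HIF1 targets, 3 rose, 16 fell and 3 did not pass, with a median of -0.58 (adjusted p = 4.87e-10). Glucose and lactate transport genes had a median of -0.39, with 0 higher, 4 lower and 3 not passing (adjusted p = 0.000816, or 0.122 with an estimated correlation). Of 16 PFKFB and glycogen genes, 1 rose, 10 fell and 5 did not pass (median -0.26, adjusted p = 7.88e-06). The median of pentose phosphate pathway genes was -0.35, from 0 higher, 6 lower and 2 not passing (adjusted p = 7.16e-06). Among pyruvate dehydrogenase regulation genes, 1 rose, 8 fell and 4 did not pass, with a median of -0.15 (adjusted p = 0.000500). TCA cycle genes had a median of -0.15, with 1 higher, 15 lower and 5 not passing (adjusted p = 1.40e-06, or 0.119 with an estimated correlation). Of 54 nuclear-encoded respiratory chain genes, 0 rose, 35 fell and 19 did not pass (median -0.14, adjusted p = 3.22e-10, or 0.119 with an estimated correlation). The median of gluconeogenesis and glyceroneogenesis genes was -0.49, from 0 higher, 6 lower and 0 not passing (adjusted p = 1.66e-06). In glycolysis Pfkl (-1.38), Ldha (-1.36), Gapdh (-1.13) and Aldoa (-1.06) fell. Pdk1 (-1.33) fell and the phosphatase gene Pdp1, which opposes it, rose (1.15). Slc2a4, the insulin-responsive glucose carrier gene, fell from 50.1 to 28.0 RPKM. Pck1 (-1.28), Gpd1 (-0.83) and the glycogen synthase gene Gys1 (-0.66) were lower. Glucose and lactate transport genes that fell were Bsg, Slc16a1, Slc16a3 and Slc2a4. Members that rose while most of their list fell were Hk1 and Ldhb (glycolysis enzymes), Adm, Hif1a and Ndrg1 (hypoxia and HIF1 targets), Pgm2 (PFKFB and glycogen) and Pdp1 (pyruvate dehydrogenase regulation). To these add Idh2 (TCA cycle).

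Among cholesterol synthesis genes, 0 rose, 22 fell and 0 did not pass, with a median of -0.60 (adjusted p = 1.22e-18). Fatty acid and triglyceride synthesis genes had a median of -0.59, with 0 higher, 15 lower and 3 not passing (adjusted p = 1.52e-14). Of 12 lipolysis and lipid droplet genes, 0 rose, 11 fell and 1 did not pass (median -0.31, adjusted p = 3.39e-09). The median of fatty acid oxidation genes was -0.16, from 1 higher, 14 lower and 5 not passing (adjusted p = 7.43e-07, or 0.0548 with an estimated correlation). Among adipocyte markers, 0 rose, 14 fell and 7 did not pass, with a median of -0.32 (adjusted p = 1.43e-08). Thermogenic and brown fat genes had a median of -0.38, with 0 higher, 5 lower and 4 not passing (adjusted p = 0.000149). Of 30 ER stress and ATF4 targets, 4 rose, 22 fell and 4 did not pass (median -0.25, adjusted p = 9.16e-11). The median of NRF2 targets was -0.13, from 2 higher, 9 lower and 8 not passing (adjusted p = 0.000245). Among circadian clock genes, 1 rose, 9 fell and 6 did not pass, with a median of -0.21 (adjusted p = 0.000916). MYC target and ribosome biogenesis genes had a median of -0.071, with 0 higher, 6 lower and 18 not passing (adjusted p = 0.0237, or 0.122 with an estimated correlation). Scd1, a desaturase gene, fell from 6331 to 3572 RPKM, with Thrsp (-1.02), Dgat2 (-0.75) and the regulator Insig1 (-0.80). The lipase inhibitor gene G0s2 (-1.28), Bscl2 (-0.93) and the hormone gene Retn (-0.71) fell too, as did Trib3 (-1.70) and Hmox1 (-1.03) of the stress lists. Thermogenic and brown fat genes that fell were Cidea, Cox7a1, Cox8b, Gk and Ppargc1b. Risen members of these lists were Cpt1a (fatty acid oxidation), Calr, Hsp90b1, Pdia4 and Pdia6 (ER stress and ATF4 targets), Nqo1 and Txnrd1 (NRF2 targets) and Nr1d2 (circadian clock).

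Of 34 extracellular matrix genes, 32 rose, 0 fell and 2 did not pass (median 0.61, adjusted p = 4.75e-18). The median of fibroblast and preadipocyte markers was 0.71, from 20 higher, 0 lower and 2 not passing (adjusted p = 1.52e-14). Among myofibroblast and contractile genes, 9 rose, 2 fell and 2 did not pass, with a median of 0.44 (adjusted p = 0.000228, or 0.122 with an estimated correlation). Wnt pathway genes had a median of 0.29, with 12 higher, 0 lower and 6 not passing (adjusted p = 9.64e-05, or 0.103 with an estimated correlation). Of 18 NF-kB and inflammatory cytokine genes, 13 rose, 1 fell and 4 did not pass (median 0.59, adjusted p = 1.40e-06). The median of interferon response genes was 0.57, from 17 higher, 0 lower and 12 not passing (adjusted p = 7.88e-06, or 0.257 with an estimated correlation). Among immediate early genes, 15 rose, 1 fell and 5 did not pass, with a median of 0.52 (adjusted p = 0.000125, or 0.148 with an estimated correlation). Lysosome genes had a median of 0.19, with 17 higher, 3 lower and 10 not passing (adjusted p = 1.62e-05). Of 47 ribosomal proteins, 12 rose, 1 fell and 34 did not pass (median 0.056, adjusted p = 0.0464, or 0.513 with an estimated correlation). Timp2 (1.44), Lox (1.12), Mmp2 (1.138) and Col12a1 (1.54) rose among matrix genes and Dcn (1.45), Postn (1.23), Pdgfra (1.10) and Vim (0.64) among fibroblast markers. The chemokine genes Cxcl5 (1.497), Ccl2 (1.37) and Cxcl12 (0.96) and the antiviral gene Bst2 (1.57) were higher. Fallen members of these lists included Tgfb1 (myofibroblast and contractile), C3 (NF-kB and inflammatory cytokines), Atf3 (immediate early genes) and Ctsl, Neu1 and Tfeb (lysosome). To these add Rps19 (ribosomal proteins).

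Adjusted over the list alone, 27 of 30 ER stress and ATF4 targets, 5 of 24 MYC target and ribosome biogenesis genes, 15 of 18 NF-kB and inflammatory cytokine genes and 12 of 19 NRF2 targets passed. Likewise 12 of 16 PFKFB and glycogen genes, 17 of 21 TCA cycle genes, 13 of 18 Wnt pathway genes and 15 of 21 adipocyte markers passed. Likewise 17 of 18 fatty acid and triglyceride synthesis genes, 22 of 29 interferon response genes, 24 of 30 lysosome genes and 39 of 54 nuclear-encoded respiratory chain genes passed. So did 12 of 47 ribosomal proteins and 6 of 9 thermogenic genes. Other called lists kept theirs. Of 28 called lists, 18 kept their call with an estimated correlation, those given with 1 adjusted p. The call of ribosomal proteins was lost with pseudocount 1, median-ratio scaling and the 20-read filter and without control replicate 1, knockdown replicate 1 or knockdown replicate 2. That of Pes1, a ribosome biogenesis gene (-0.087), was lost with quantile normalization, voom and a model of this comparison alone, and without control replicate 2 or knockdown replicate 1. Without control replicate 2 or a filter heat shock passed. Lists not called were FoxO target and insulin signalling genes (median -0.031, adjusted p = 0.299), Foxk family and Sin3 partner genes (median -0.052, adjusted p = 0.171) and autophagy genes (median -0.0032, adjusted p = 0.397). There was no call for cell cycle genes (median 0.099, adjusted p = 0.171), heat shock genes (median -0.090, adjusted p = 0.107) and macrophage markers (median 0.011, adjusted p = 0.764). There was no call for mitochondrially encoded transcripts (median 0.19, adjusted p = 0.125), p53 targets (median 0.014, adjusted p = 0.800) and replication-dependent histones (median -0.066, adjusted p = 0.299). Median and mean differed in sign for p53 targets (median 0.014, mean -0.011, tested lower).

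In Foxk2 overexpression Cyp2b10, Cidea and Acaa1b were among the most raised genes and Ccdc80, Car3 and Cyp2e1 among the most lowered. Cidea rose from 1.24 ± 0.430 to 34.4 ± 4.37 RPKM (SD, n = 2 and 2; log2 fold change 4.34 ± 0.14 SE, adjusted p = 4.72e-12), and the cytochrome gene Cyp2b10 from 1.996 ± 0.119 to 54.1 ± 6.57 RPKM (4.45 ± 0.093; ENSMUSG00000030483.14, chromosome 7, 25897620 to 25926624). Apoc1, an apolipoprotein gene, rose from 72.4 ± 6.504 to 487 ± 5.07 RPKM (2.75 ± 0.063). Ccdc80, a secreted matrix protein gene, fell from 582 ± 9.50 to 57.6 ± 0.315 RPKM (-3.33 ± 0.080, adjusted p = 4.23e-13; ENSMUSG00000022665.14, chromosome 16, 45093402 to 45128077).

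In total 7188 of 15981 genes changed (3678 higher, 3510 lower), with 246 rises and 379 falls of at least 2-fold. The ranges of the groups were apart for 70.3% of genes tested, where chance gives 33.3%. The peroxisomal thiolase gene Acaa1b (3.44), Aspg (3.13), Gfra1 (3.10), Hgd, which degrades tyrosine (3.04), and haem-binding Hpx (2.43) rose. The carbonic anhydrase gene Car3 (-3.09), Cyp2e1 (-2.79), Clec3b (-2.71), Thbd (-2.57), Ang5 (-2.51), Thbs1 (-2.50) and Lum (-2.47) fell.

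The median of glycolysis enzymes was 0.91, from 14 higher, 2 lower and 1 not passing (adjusted p = 6.57e-07, or 0.154 with an estimated correlation). Among hypoxia and HIF1 targets, 17 rose, 1 fell and 4 did not pass, with a median of 0.48 (adjusted p = 6.35e-07, or 0.154 with an estimated correlation). Glucose and lactate transport genes had a median of 0.40, with 5 higher, 1 lower and 1 not passing (adjusted p = 0.0198, or 0.319 with an estimated correlation). Of 16 PFKFB and glycogen genes, 9 rose, 1 fell and 6 did not pass (median 0.25, adjusted p = 0.00284, or 0.154 with an estimated correlation). The median of pentose phosphate pathway genes was 0.30, from 5 higher, 1 lower and 2 not passing (adjusted p = 0.0143, or 0.286 with an estimated correlation). Among pyruvate dehydrogenase regulation genes, 9 rose, 4 fell and 0 did not pass, with a median of 0.46 (adjusted p = 0.00796, or 0.154 with an estimated correlation). TCA cycle genes had a median of 0.43, with 16 higher, 2 lower and 3 not passing (adjusted p = 9.32e-08, or 0.154 with an estimated correlation). Of 54 nuclear-encoded respiratory chain genes, 53 rose, 0 fell and 1 did not pass (median 0.54, adjusted p = 3.43e-23, or 0.154 with an estimated correlation). Hk2 (1.251), Gapdh (1.38), Eno1 (1.06) and Pfkp (1.02) rose in glycolysis, and the glycogen-targeting gene Ppp1r3b by 2.18 ± 0.11. Egln3 (2.14), Ak4 (2.17), P4ha1 (1.40) and Pdk1 (1.31) rose among hypoxia genes. The pyruvate carrier gene Mpc2 (0.99), Tkt (1.29), Idh3a (1.17) and Sdhb (1.002) were higher. Raised were Bsg, Slc16a1, Slc16a3, Slc2a1 and Slc2a4 (glucose and lactate transport) and G6pdx, Pgd, Rpe, Taldo1 and Tkt (pentose phosphate pathway). Lowered members of these lists were Eno3 and Hk1 (glycolysis enzymes), Adm (hypoxia and HIF1 targets), Slc2a8 (glucose and lactate transport) and Pygb (PFKFB and glycogen). To these add H6pd (pentose phosphate pathway), Pdk2, Pdk3, Pdp1 and Pdpr (pyruvate dehydrogenase regulation) and Idh1 and Idh2 (TCA cycle).

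The median of thermogenic and brown fat genes was 1.55, from 7 higher, 1 lower and 1 not passing (adjusted p = 3.57e-05, or 0.154 with an estimated correlation). Among fatty acid and triglyceride synthesis genes, 14 rose, 1 fell and 3 did not pass, with a median of 0.47 (adjusted p = 6.35e-07, or 0.154 with an estimated correlation). Fatty acid oxidation genes had a median of 0.37, with 15 higher, 4 lower and 1 not passing (adjusted p = 0.000263, or 0.198 with an estimated correlation). Of 22 cholesterol synthesis genes, 16 rose, 1 fell and 5 did not pass (median 0.51, adjusted p = 5.37e-08, or 0.198 with an estimated correlation). The median of ER stress and ATF4 targets was 0.30, from 19 higher, 4 lower and 7 not passing (adjusted p = 0.000151, or 0.181 with an estimated correlation). Among cell cycle genes, 19 rose, 2 fell and 12 did not pass, with a median of 0.26 (adjusted p = 0.00206, or 0.252 with an estimated correlation). Ribosomal proteins had a median of 0.25, with 30 higher, 2 lower and 15 not passing (adjusted p = 8.50e-07, or 0.198 with an estimated correlation). Cox8b (1.92), Gk (1.55) and Elovl3 (2.21) rose with the thermogenic list, Dgat2 (1.83), Elovl6 (2.15) and Elovl5 (1.52) with lipid synthesis, and Cyp51 (1.71) with sterol synthesis. Adipocyte products moved both ways, Adipoq (-1.29), Cidec (-1.43) and the lipase gene Lipe (-0.72) down and Retn (1.10) up. Falling where most of the list rose were Adrb3 (thermogenic and brown fat), Srebf1 (fatty acid and triglyceride synthesis), Acads, Cpt1a, Ech1 and Eci1 (fatty acid oxidation) and Insig1 (cholesterol synthesis). To these add Mthfd2, Pdia4, Phgdh and Xbp1 (ER stress and ATF4 targets), E2f1 and Mcm7 (cell cycle) and Rpl5 and Rps4x (ribosomal proteins).

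Of 34 extracellular matrix genes, 2 rose, 27 fell and 5 did not pass (median -0.85, adjusted p = 4.26e-14, or 0.154 with an estimated correlation). The median of fibroblast and preadipocyte markers was -0.99, from 0 higher, 19 lower and 3 not passing (adjusted p = 6.68e-14, or 0.154 with an estimated correlation). Among myofibroblast and contractile genes, 0 rose, 10 fell and 3 did not pass, with a median of -0.44 (adjusted p = 6.16e-05, or 0.156 with an estimated correlation). Wnt pathway genes had a median of -0.65, with 0 higher, 12 lower and 6 not passing (adjusted p = 2.94e-05, or 0.154 with an estimated correlation). Of 21 immediate early genes, 3 rose, 14 fell and 4 did not pass (median -0.50, adjusted p = 0.000407, or 0.252 with an estimated correlation). The median of interferon response genes was -0.38, from 0 higher, 9 lower and 20 not passing (adjusted p = 0.0176, or 0.636 with an estimated correlation). Mmp2 (-2.10), Dcn (-2.14), Pdgfra (-1.82), Postn (-1.58) and Col6a3 (-1.23) fell, and so did the transcription factor genes Lef1 (-1.37), Egr1 (-1.30) and Klf6 (-0.82). Rising where most of the list fell were Col11a1 and Tnc (extracellular matrix) and Atf3, Fosl2 and Nr4a1 (immediate early genes).

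Calls adjusted over the list alone numbered 24 of 30 ER stress and ATF4 targets, 11 of 16 PFKFB and glycogen genes, 23 of 33 cell cycle genes and 31 of 34 extracellular matrix genes. Others were 16 of 18 fatty acid and triglyceride synthesis genes, 18 of 21 immediate early genes and 8 of 29 interferon response genes. Further counts were 54 of 54 nuclear-encoded respiratory chain genes (53 higher, 1 lower), 34 of 47 ribosomal proteins and 9 of 9 thermogenic genes. Other called lists kept theirs. With an estimated correlation no list kept its call. The interferon call was lost without control replicate 2 or overexpression replicate 1, and calls of the pentose phosphate and pyruvate dehydrogenase lists in a model of this comparison alone (pentose phosphate also in that of the factor). Without a filter the adipocyte, lysosome and histone lists passed, the first also without overexpression replicate 1. The interferon genes Gbp2 (-0.45) and Ifit3b (-1.17) lost theirs in a model of this comparison alone (Gbp2 also in that of the factor) and without control replicate 2, and without overexpression replicate 1 and replicate 2 in turn. Lists without a call were FoxO target and insulin signalling genes (median 0.0044, adjusted p = 0.991), Foxk family and Sin3 partner genes (median 0.013, adjusted p = 0.935) and MYC target and ribosome biogenesis genes (median 0.052, adjusted p = 0.931). Camera did not call NF-kB and inflammatory cytokine genes (median -0.13, adjusted p = 0.228), NRF2 targets (median 0.042, adjusted p = 0.849) and adipocyte markers (median -0.48, adjusted p = 0.0650). Not passing were autophagy genes (median -0.0080, adjusted p = 0.343), circadian clock genes (median 0.16, adjusted p = 0.643) and gluconeogenesis and glyceroneogenesis genes (median 0.12, adjusted p = 0.334). Camera did not call heat shock genes (median 0.040, adjusted p = 0.850), lipolysis and lipid droplet genes (median -0.046, adjusted p = 0.871) and lysosome genes (median -0.23, adjusted p = 0.109). Not passing were macrophage markers (median -0.055, adjusted p = 0.643), mitochondrially encoded transcripts (median -0.091, adjusted p = 0.964) and p53 targets (median 0.076, adjusted p = 0.343). Camera did not call replication-dependent histones (median -0.44, adjusted p = 0.0724). Signs of the median, mean and test differed for FoxO target and insulin signalling genes (median 0.0044, mean -0.015, tested lower), Foxk family and Sin3 partner genes (median 0.013, mean 0.0012, tested lower) and lipolysis and lipid droplet genes (median -0.046, mean 0.28, tested lower).

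Foxk2 knockdown raised most measured matrix and fibroblast transcripts and lowered fatty acid and triglyceride synthesis transcripts. Pdgfra rose from 15.7 ± 0.0763 to 62.7 ± 4.86 RPKM (SD, n = 2 and 2; log2 fold change 1.96 ± 0.068 SE, adjusted p = 4.67e-11) and Mmp2 from 57.0 ± 1.88 to 203 ± 4.23 RPKM (1.82 ± 0.065; ENSMUSG00000031740.8, chromosome 8, 92827291 to 92853420). Cidea fell from 3.85 ± 0.327 to 0.221 ± 0.00343 RPKM (-2.59 ± 0.14) and Apoc1 from 183 ± 3.76 to 46.8 ± 0.751 RPKM (-1.96 ± 0.063; ENSMUSG00000040564.14, chromosome 7, 19689481 to 19692660).

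Calls numbered 5386 among 15981 genes, 2879 higher and 2507 lower, and 318 rises and 60 falls reached 2-fold. After removal of a length and GC trend per library, 2224 were higher and 3390 lower, 39.6% in place of 53.5% higher. Both other scalings reversed the split too. Between the groups 67.2% of genes tested had ranges apart (33.3% by chance). The amino acid carrier gene Slc36a2 (-2.01), Pck1, which feeds glycerol synthesis (-1.71), Cmbl (-1.76), the histone gene Hist1h2bk (-1.81) and Odf3l1 (-1.56) fell.

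The 8 largest rises passing the rule were mitochondrial transcripts, mt-Nd3 (5.24), mt-Atp6 (4.80), mt-Co3 (4.72), mt-Co2 (4.62), mt-Nd4l (4.59), mt-Atp8 (4.03), mt-Tg (4.02) and mt-Tk (3.99). These are uncertain. The gene mt-Nd3 had 87 to 725 reads in the knockdown controls, 10523 to 12753 in the overexpression controls and 1056 to 10508 in Foxk2 overexpression. Annotated near-identical nuclear copies cover at least 99% of mt-Nd3, mt-Atp6, mt-Co3, mt-Co2 and mt-Nd4l and none of mt-Atp8. The short transfer RNA genes mt-Tg and mt-Tk had 2 to 6 and 1 to 6 reads in the knockdown controls.

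Among fibroblast and preadipocyte markers, 20 rose, 0 fell and 2 did not pass, with a median of 1.19 (adjusted p = 7.26e-21). Extracellular matrix genes had a median of 0.90, with 32 higher, 0 lower and 2 not passing (adjusted p = 7.74e-27). Of 13 myofibroblast and contractile genes, 11 rose, 0 fell and 2 did not pass (median 0.84, adjusted p = 5.60e-09, or 0.0528 with an estimated correlation). The median of Wnt pathway genes was 0.47, from 14 higher, 0 lower and 4 not passing (adjusted p = 1.23e-06, or 0.0745 with an estimated correlation). Among NF-kB and inflammatory cytokine genes, 11 rose, 1 fell and 6 did not pass, with a median of 0.47 (adjusted p = 6.73e-05). Immediate early genes had a median of 0.41, with 12 higher, 1 lower and 8 not passing (adjusted p = 0.000122, or 0.188 with an estimated correlation). Of 30 lysosome genes, 15 rose, 3 fell and 12 did not pass (median 0.14, adjusted p = 0.00773, or 0.193 with an estimated correlation). The median of ribosomal proteins was 0.16, from 24 higher, 0 lower and 23 not passing (adjusted p = 3.00e-05, or 0.214 with an estimated correlation). Dcn (2.11), Lox (1.75), Postn (1.69), Fn1 (1.66), Timp2 (1.54) and the smooth muscle actin gene Acta2 (1.44) rose. Cxcl12 (1.51), the growth factor gene Csf1 (1.06) and Junb (1.2) rose as well, with the protease gene Ctsk (1.00) of lysosomes. Members that fell in these lists included C3 (NF-kB and inflammatory cytokines), Atf3 (immediate early genes) and Atp6v1h and Lipa (lysosome).

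Among fatty acid and triglyceride synthesis genes, 0 rose, 18 fell and 0 did not pass, with a median of -0.58 (adjusted p = 6.56e-15). Fatty acid oxidation genes had a median of -0.30, with 1 higher, 16 lower and 3 not passing (adjusted p = 5.36e-09, or 0.0569 with an estimated correlation). Of 22 cholesterol synthesis genes, 0 rose, 17 fell and 5 did not pass (median -0.42, adjusted p = 7.61e-10, or 0.125 with an estimated correlation). The median of lipolysis and lipid droplet genes was -0.11, from 2 higher, 6 lower and 4 not passing (adjusted p = 0.0112, or 0.227 with an estimated correlation). Among thermogenic and brown fat genes, 1 rose, 5 fell and 3 did not pass, with a median of -0.60 (adjusted p = 0.00155, or 0.0745 with an estimated correlation). Adipocyte markers had a median of -0.17, with 3 higher, 9 lower and 9 not passing (adjusted p = 0.00123, or 0.113 with an estimated correlation). Of 30 ER stress and ATF4 targets, 1 rose, 18 fell and 11 did not pass (median -0.16, adjusted p = 9.59e-06, or 0.0921 with an estimated correlation). The median of NRF2 targets was -0.15, from 2 higher, 9 lower and 8 not passing (adjusted p = 0.00224, or 0.0853 with an estimated correlation). Dgat2 (-1.39) and Thrsp (-1.03) fell with lipid synthesis, Elovl3 (-1.56) and Cox8b (-1.10) with the thermogenic genes, and Retn (-0.96) and Slc2a4 (-0.91) with adipocyte markers. Thermogenic and brown fat genes that fell were Cidea, Cox7a1, Cox8b, Elovl3 and Gk. Higher than controls in these lists were Cpt1a (fatty acid oxidation), Lipe and Plin4 (lipolysis and lipid droplet), Adrb3 (thermogenic and brown fat) and Adrb3, Cd36 and Lipe (adipocyte markers). To these add Calr (ER stress and ATF4 targets) and Gstm1 and Nqo1 (NRF2 targets).

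Among glycolysis enzymes, 4 rose, 9 fell and 4 did not pass, with a median of -0.23 (adjusted p = 0.00896, or 0.360 with an estimated correlation). Hypoxia and HIF1 targets had a median of -0.27, with 4 higher, 11 lower and 7 not passing (adjusted p = 0.0132, or 0.328 with an estimated correlation). Of 16 PFKFB and glycogen genes, 0 rose, 9 fell and 7 did not pass (median -0.26, adjusted p = 5.57e-05, or 0.0528 with an estimated correlation). The median of pentose phosphate pathway genes was -0.42, from 0 higher, 5 lower and 3 not passing (adjusted p = 0.00114, or 0.137 with an estimated correlation). Among pyruvate dehydrogenase regulation genes, 1 rose, 9 fell and 3 did not pass, with a median of -0.39 (adjusted p = 4.19e-05). TCA cycle genes had a median of -0.27, with 1 higher, 18 lower and 2 not passing (adjusted p = 2.44e-09, or 0.0853 with an estimated correlation). Of 54 nuclear-encoded respiratory chain genes, 0 rose, 46 fell and 8 did not pass (median -0.25, adjusted p = 5.02e-17, or 0.0745 with an estimated correlation). The median of gluconeogenesis and glyceroneogenesis genes was -0.47, from 0 higher, 4 lower and 2 not passing (adjusted p = 0.00172, or 0.125 with an estimated correlation). Among mitochondrially encoded transcripts, 8 rose, 1 fell and 4 did not pass, with a median of 0.49 (adjusted p = 0.0498, or 0.368 with an estimated correlation). Hk2 (-0.69), Pfkp (-0.68) and Ldha (-0.70) fell while Ldhb rose (0.35), and Egln3 (-1.26), Pdk1 (-0.88) and Tkt (-0.81) fell. Fallen were G6pdx, Pgd, Rpe, Taldo1 and Tkt (pentose phosphate pathway) and Gk, Gpd1, Pck1 and Pcx (gluconeogenesis and glyceroneogenesis). Higher in spite of a lower list were Eno2, Eno3, Hk1 and Ldhb (glycolysis enzymes), Adm, Hif1a, Ndrg1 and P4ha2 (hypoxia and HIF1 targets), Pdp1 (pyruvate dehydrogenase regulation) and Idh2 (TCA cycle). Among mitochondrially encoded transcripts mt-Cytb fell.

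The counts adjusted over the list alone were 10 of 16 PFKFB and glycogen genes, 18 of 22 cholesterol synthesis genes, 5 of 6 gluconeogenesis and glyceroneogenesis genes and 14 of 17 glycolysis enzymes. Further ones were 16 of 22 hypoxia and HIF1 targets, 14 of 21 immediate early genes and 19 of 30 lysosome genes. Mitochondrially encoded transcripts gave 11 of 13 (8 higher, 3 lower). Further ones were 6 of 8 pentose phosphate pathway genes, 48 of 54 nuclear-encoded respiratory chain genes and 26 of 47 ribosomal proteins. For other called lists they did not differ. The calls that held with an estimated correlation were the 5 of NF-kB and inflammatory cytokine genes, extracellular matrix genes, fatty acid and triglyceride synthesis genes, fibroblast and preadipocyte markers and pyruvate dehydrogenase regulation genes. A model of this comparison alone ended the calls of the hypoxia, lipolysis and mitochondrial lists, of Scd1, Pcx and of each mitochondrial gene named except mt-Tg. In a model of the factor the lipolysis and mitochondrial lists, Scd1, mt-Atp8, mt-Nd4l and mt-Tk lost theirs. The mitochondrial list also lost its call with pseudocount 0.1, both stricter filters, both other scalings and voom, and without knockdown replicate 2 or control replicate 2, and mt-Tk without control replicate 2. Glucose transport and interferon lists passed without control replicate 1, interferon without knockdown replicate 1 and autophagy without control replicate 2, all these and FoxO targets without a filter, and macrophage markers in both smaller models. Camera made no call for FoxO target and insulin signalling genes (median 0.18, adjusted p = 0.0875), Foxk family and Sin3 partner genes (median 0.12, adjusted p = 0.380) and MYC target and ribosome biogenesis genes (median -0.022, adjusted p = 0.488). It made none for autophagy genes (median -0.062, adjusted p = 0.0808), cell cycle genes (median -0.080, adjusted p = 0.488) and circadian clock genes (median 0.019, adjusted p = 0.994). It made none for glucose and lactate transport genes (median -0.12, adjusted p = 0.0565), heat shock genes (median 0.026, adjusted p = 0.771) and interferon response genes (median 0.37, adjusted p = 0.0875). It made none for macrophage markers (median 0.25, adjusted p = 0.101), p53 targets (median -0.070, adjusted p = 0.279) and replication-dependent histones (median 0.039, adjusted p = 0.726). Signs differed between median, mean and test for Foxk family and Sin3 partner genes (median 0.12, mean -0.020, tested higher), circadian clock genes (median 0.019, mean -0.012, tested lower), heat shock genes (median 0.026, mean -0.022, tested lower) and replication-dependent histones (median 0.039, mean 0.034, tested lower).

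Endothelial, epithelial and skeletal muscle marker lists had 0, 1 and 2 measured genes and were not tested. Krt18 of epithelia rose in the labelled Foxk1 overexpression (0.74) and in Foxk2 overexpression and fell in the knockdowns (-0.94 with Foxk1, -0.84 with Foxk2). Des of muscle rose in both (0.65 and 1.13) and fell in the knockdowns (-0.70 and -0.71), and Acta1 fell in the labelled Foxk1 overexpression (-0.67).

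Many genes changed in opposite directions in the 2 Foxk1 comparisons, given here with the labelled overexpression, in which Foxk1 itself was lower, first. Lower and then higher were Thbs1 (-1.70 and 1.89), Itgbl1 (-3.48 and 1.48), Dcn (-2.73 and 1.45), Timp2 (-2.15 and 1.44), Gem (-1.97 and 1.41) and Clec3b (-4.00 and 1.40). Higher and then lower were Ak4 (1.69 and -2.44), Chchd10 (2.18 and -1.36), Sema3g (1.31 and -1.64), Cox6a2 (1.27 and -1.46), G0s2 (1.254 and -1.28) and Stbd1 (1.44 and -1.252). Both comparisons raised mt-Ti (0.65 and 0.62), Wfdc21 (0.73 and 0.59), Csrp2 (0.93 and 0.46), Tubb6 (0.60 and 0.44), Col27a1 (0.67 and 0.43) and Ppp1r12b (0.39 and 0.47). Both lowered Snord42a (-0.94 and -1.02), Tmem179 (-0.69 and -0.75), Cidec (-1.004 and -0.67), Smkr-ps (-0.61 and -0.81), Pnpla3 (-0.57 and -1.03) and Rgr (-0.56 and -0.67).

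Of 3968 genes called in both, 3414 (86.0%) had opposite directions and 554 the same. Independent lists would give 1370 and 1372. An exact binomial test against equal shares, with genes as units although they are not independent, gave log10 p = -499.2, and across genes Pearson's r was -0.482 and Spearman's rho -0.430.

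For Foxk2, overexpression raised and knockdown lowered Cidea (4.34 and -2.59), Slc36a2 (2.06 and -2.01), Apoc1 (2.75 and -1.96), Pck1 (1.80 and -1.71), Cmbl (1.70 and -1.76) and Elovl3 (2.21 and -1.56). The reverse held for Dcn (-2.14 and 2.11), Clec3b (-2.71 and 1.99), Mmp2 (-2.10 and 1.82), Pdgfra (-1.82 and 1.96), Ptn (-1.82 and 2.13) and Cd248 (-2.09 and 1.79). Both manipulations raised Pmepa1 (0.96 and 1.12), Id2 (0.95 and 0.75), Cdon (0.60 and 0.73), Fbln5 (0.56 and 0.95), Chd3 (0.49 and 0.86) and Ndrg2 (0.94 and 0.41). Lower in both were Hist1h2bk (-1.12 and -1.81), Morc4 (-0.64 and -0.64), Fmo5 (-0.997 and -0.62), Aqp1 (-0.67 and -0.56), Sncg (-0.52 and -0.82) and Mfsd13a (-0.57 and -0.51). Opposite directions were seen in 3522 of 3859 genes called in both (91.3%, 1209 expected of independent lists) and the same direction in 337 (1213 expected). The exact binomial log10 p was -666.4, and across genes r was -0.573 and rho -0.539.

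**Figure D4:**
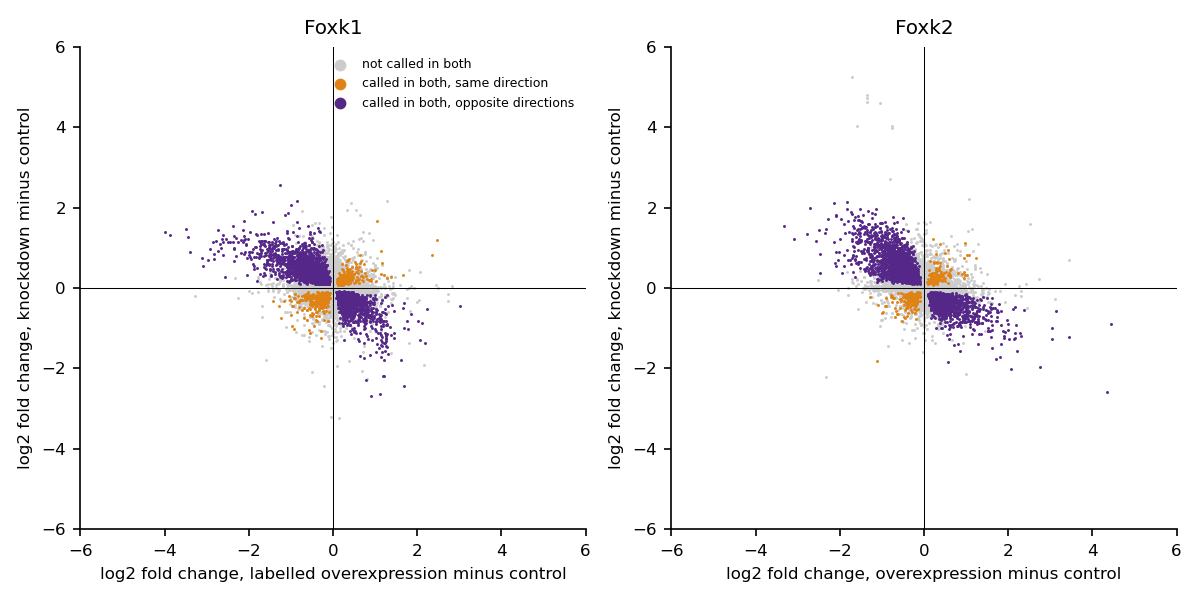
Log2 fold change of each tested gene in overexpression (x axis) and knockdown (y axis) of Foxk1, where the x axis is the label only, and of Foxk2, coloured by whether both comparisons called it.

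The labelled Foxk1 overexpression and Foxk2 overexpression both raised Cidea (3.02 and 4.34), Gfra1 (2.34 and 3.10), Aspg (2.24 and 3.13), Elovl3 (2.73 and 2.21), Cyp2b10 (1.93 and 4.45) and Atp2a3 (2.07 and 1.77). They both lowered Clec3b (-4.00 and -2.71), Lum (-2.74 and -2.47), Ear2 (-2.92 and -2.33), Dcn (-2.73 and -2.14), Apcdd1 (-2.56 and -2.11) and Mmp2 (-2.26 and -2.10). Higher with the Foxk1 label and lower in Foxk2 overexpression were Smim27 (0.46 and -0.42), Tmc6 (0.40 and -0.75), Myc (0.38 and -0.53), Ffar2 (0.37 and -0.43), Aqp1 (0.36 and -0.67) and Zkscan17 (0.36 and -0.34). The reverse was seen for Mir186 (-0.72 and 0.94), Plscr4 (-0.61 and 0.71), Tmem140 (-0.67 and 0.55), Rora (-0.77 and 0.53), Ucp3 (-0.51 and 0.50) and Rab40b (-0.55 and 0.46). The same direction held for 4389 of 4763 genes called in both, against 1719 for independent lists, and opposite directions for 374 against 1719. Across genes r was 0.616.

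Both knockdowns raised Bst2 (1.57 and 1.53), Aebp1 (1.49 and 1.58), Itgbl1 (1.48 and 1.69), Dcn (1.45 and 2.11), Timp2 (1.44 and 1.54) and Thbs1 (1.89 and 1.44). Both lowered Odf3l1 (-1.58 and -1.56), Pck1 (-1.28 and -1.71), Cmbl (-1.28 and -1.76), Egln3 (-2.69 and -1.26), Ak4 (-2.44 and -1.23) and Slc25a34 (-1.59 and -1.21). Foxk1 knockdown raised and Foxk2 knockdown lowered Aqp1 (0.71 and -0.56), Ubd (0.69 and -0.49), Gbp2 (0.48 and -0.74), Mlkl (0.42 and -0.48), Rbm43 (0.34 and -0.39) and Bbip1 (0.32 and -0.36). Foxk1 knockdown lowered and Foxk2 knockdown raised Mmp11 (-0.75 and 0.76), P2rx3 (-0.49 and 0.48), Dmpk (-0.47 and 0.47), Fam107a (-0.42 and 0.58), Pltp (-0.37 and 0.41) and Peg10 (-0.35 and 0.41). Of 3276 genes called in both, 3079 shared the direction (975.4 expected) and 197 did not (957.1 expected), with r = 0.513 across genes.

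Effect sizes of the 2 factors were compared by a test of their difference, Foxk1 minus Foxk2. In overexpression Apoc1 (-2.24 ± 0.082, adjusted p = 3.13e-10), Ogn (-2.14 ± 0.096, adjusted p = 2.34e-09), Acaa1b (-2.71 ± 0.15, adjusted p = 2.14e-08) and Pi15 (-2.23 ± 0.12, adjusted p = 1.45e-08) differed among named genes. In knockdown Apoa4 (-3.93 ± 0.21, adjusted p = 6.09e-08), Cidea (2.14 ± 0.18, adjusted p = 4.01e-06) and Egln3 (-1.43 ± 0.19, adjusted p = 0.000137) differed, SE after the sign. The size for Cidea is uncertain: it had 5 to 8 reads in Foxk1 knockdown controls, where the pseudocount understates its fall with Foxk1. Differences passed for 4019 genes in overexpression and 2287 in knockdown. Each crosses the sets of libraries that the first principal component parts, and in overexpression also the label under which Foxk1 fell.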

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

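Among the tests in this part, those of the trend on gene length and GC content and of other splits were set out before their results were seen, though the trend was added after the data were examined, and all others were chosen after. Genes with 0 reads in every compared library of 1 factor, such as mt-Tg in knockdown, are left out. What brought the following values here is a tested difference between the effects of Foxk1 and Foxk2 under the same manipulation, given as Foxk1 minus Foxk2 in log2 units, each with an adjusted p under 0.05. In overexpression it compares libraries labelled Foxk1 overexpression, where Foxk1 fell, with Foxk2 overexpression, and 4019 genes differed. Among lists the median difference in overexpression, which passed for 11 lists and for 0 with an estimated correlation, was above 0 for immediate early genes (0.37), MYC target and ribosome biogenesis genes (0.25), cell cycle genes (0.21) and ribosomal proteins (0.062). It was below 0 for fatty acid oxidation genes (-0.15), pyruvate dehydrogenase regulation genes (-0.19), TCA cycle genes (-0.23) and cholesterol synthesis genes (-0.26). Below 0 too were fatty acid and triglyceride synthesis genes (-0.29), nuclear-encoded respiratory chain genes (-0.30) and thermogenic and brown fat genes (-0.73). Of the targets and the genes of largest rise or fall, those above 0 include Ang5 (1.77), Ccdc80 (1.34), Adm2 (1.32), Car3 (0.99), Thbd (0.86) and Cyp2e1 (0.85). To these add Thbs1 (0.80), Ddit4 (0.61), Elovl3 (0.52) and Foxk1 (0.38). Those below 0 include Foxk2 (-0.28), Gfra1 (-0.76), Aspg (-0.89), Hpx (-1.27), Clec3b (-1.29), Cidea (-1.32) and Scara3 (-1.38). Also below 0 were Ptn (-1.63), Itgbl1 (-1.82), Hgd (-2.01), Ogn (-2.14), Pi15 (-2.23), Apoc1 (-2.24), Cyp2b10 (-2.52) and Acaa1b (-2.71). Differences near the pseudocount are uncertain, as for Adm2 (1 to 24 reads in the compared Foxk2 libraries).

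In knockdown 2287 genes differed. Among lists the median difference in knockdown, which passed for 15 lists and for 0 with an estimated correlation, was above 0 for interferon response genes (0.201), nuclear-encoded respiratory chain genes (0.14), TCA cycle genes (0.13) and fatty acid oxidation genes (0.12). It was below 0 for ribosomal proteins (-0.079), FoxO target and insulin signalling genes (-0.13), circadian clock genes (-0.15) and ER stress and ATF4 targets (-0.16). Below 0 too were cholesterol synthesis genes (-0.19), lipolysis and lipid droplet genes (-0.197), hypoxia and HIF1 targets (-0.33) and myofibroblast and contractile genes (-0.36). Below 0 too were glycolysis enzymes (-0.44), extracellular matrix genes (-0.47) and fibroblast and preadipocyte markers (-0.58). Of the targets and the genes of largest rise or fall, those above 0 include Cidea (2.14), Ccl8 (1.79), Foxk2 (1.64), Grem1 (1.52), Il2ra (1.23) and Slc36a2 (1.19). To these add Apoc1 (0.96), Mmp3 (0.89), Rgs16 (0.86), Cmbl (0.49) and Thbs1 (0.45). Those below 0 include Cox7a1 (-0.996), Ak4 (-1.201), Ero1l (-1.21), Cyp2ab1 (-1.37), Egln3 (-1.43), Foxk1 (-1.53) and Apoa4 (-3.93). Also below 0 were mt-Atp8 (-4.37), mt-Nd4l (-4.40), mt-Co2 (-4.65), mt-Atp6 (-4.77), mt-Nd3 (-5.01) and mt-Co3 (-5.15). Mitochondrial genes may share reads with nuclear copies, so their differences are uncertain.

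Fibroblast and preadipocyte markers were lower in overexpression (medians -1.16 in the labelled Foxk1 one and -0.99 with Foxk2) and higher in knockdown (0.71 with Foxk1 and 1.19 with Foxk2). Both overexpression calls were lost with an estimated correlation (adjusted p = 0.0897 and 0.154). A bias from GC content or gene length as the whole cause is argued against: with the trend removed, at least 91.4% of each median remained. Undifferentiated cells could be fewer in overexpression, which lower adipocyte markers run against, and more in knockdown, which they go with. The tests leave both open. With genes as units, 12 were lower and 5 higher in the labelled Foxk1 overexpression (exact binomial p = 0.143), and 12 and 8 in Foxk2 overexpression (exact binomial p = 0.503). In Foxk1 knockdown 14 were lower and 0 higher (exact binomial p = 0.000122), and in Foxk2 knockdown 9 and 3 (exact binomial p = 0.146). Camera called these markers lower in all but Foxk2 overexpression, and with an estimated correlation in Foxk1 knockdown alone. An effect of the factors within cells is a hypothesis that these data cannot test.

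Foxk1 was not higher in the libraries labelled Foxk1 overexpression. An exchange of the 2 group labels is argued against, if effects of overexpression and knockdown are opposite: effects in these libraries and in Foxk1 knockdown correlated across genes at r = -0.482. A construct whose transcript is not counted on mouse Foxk1 is left open by the log2 fold change of -0.28, which lower transcription of the cell's own gene would also give. No table here measures the construct.

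Of 13 mitochondrial mRNAs, 6 differed several-fold between replicates of a Foxk2 group (log2 ranges of 2.83 to 3.23). The mean of the largest ranges was 2.6 for 6 mRNAs with 50% or more of their length in near-identical nuclear copies and 0.661 for 7 others, mt-Co1 at 31.3% among them (exact permutation p = 0.00874, 1716 arrangements), which is in line with reads shared with such copies, a hypothesis tested on the data that raised it. An exception was mt-Nd4, 63.6% covered with a range of 0.668. For mt-Atp8 (range 3.10) no copy was found, but the search would miss unannotated or short ones. A response to the Foxk2 level remains open: of the 6 mRNAs that vary most, 0 have a range above their knockdown effect, and all 6 have one above their overexpression effect.

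The 10 ways to split the libraries of a Foxk1 comparison, the real one included, are too few to test the grouping. The real one gave 7643 genes in the labelled Foxk1 overexpression and 5734 in Foxk1 knockdown, with at most 2 and 5 in any other.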

How the results depend on the processing

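As listed above, some alternatives were added after the data were examined. Glycolysis medians kept their direction under every alternative, and no count of changed genes, or of genes changed in opposite or the same directions, moved by 1.5 times. With the length and GC trend removed, the share of changed genes that were higher passed from above to below that of lower ones in both knockdowns (43.0% with Foxk1, 39.6% with Foxk2). Median-ratio scaling (48.8% and 48.9%) and quantile normalization (47.9% and 45.3%) reversed it as well. With other filters, pseudocounts, scalings, models and tests the counts were 6431 to 8134 in the labelled Foxk1 overexpression, 4483 to 6186 in Foxk1 knockdown, 5652 to 7964 in Foxk2 overexpression and 4605 to 6349 in Foxk2 knockdown. Of these, the smallest in each came from a model of one comparison. In the same order, the filter at 20 reads gave 7473, 5690, 7147 and 5476. Genes opposite in direction numbered 2527 to 3810 for Foxk1 and 2596 to 4153 for Foxk2, and genes of the same direction 3264 to 4850 in overexpression and 2196 to 3565 in knockdown.

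Without 1 library at a time, where a lone Foxk2 library is assumed to vary like the other groups, the counts were 6897 to 7219 in the labelled Foxk1 overexpression, 5026 to 5149 in Foxk1 knockdown, 5759 to 6237 in Foxk2 overexpression and 3868 to 4202 in Foxk2 knockdown. Opposite genes numbered 3078 to 3347 and 2706 to 3221, and genes of the same direction 3817 to 4304 and 2452 to 2980. Glycolysis medians, for the comparisons in the order first given, ranged over 0.958 to 1.07, -0.828 to -0.744, 0.821 to 0.988 and -0.283 to -0.175.

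Glycolysis enzymes lost the call with an estimated correlation in the labelled Foxk1 overexpression (1.01, adjusted p = 0.142; 1.11e-10 to 0.142 over alternatives that keep all members), Foxk2 overexpression (0.905, adjusted p = 0.154; 2.21e-09 to 0.154) and Foxk2 knockdown (-0.225, adjusted p = 0.360; 0.00230 to 0.360). Without covered members Foxk1 knockdown lost its call too (adjusted p = 0.0581). The estimate widens the test by construction where members vary together. Under it alone the number of lists called moved by over 1.5 times, to 0 in both overexpressions, 18 in Foxk1 knockdown and 5 in Foxk2 knockdown.

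Across the other lists and settings, 2642 tests stayed on their side of the threshold, 41 lost a call and 45 gained 1, and for named genes 8171 stayed and 45 lost it, none with a change of direction. Losses include ribosomal proteins in Foxk1 knockdown (median 0.023, adjusted p = 0.175), with median-ratio scaling, interferon response in Foxk2 overexpression (median -0.089, adjusted p = 0.389), without control replicate 2, and mitochondrially encoded transcripts in Foxk2 knockdown (median 0.29, adjusted p = 0.155), without knockdown replicate 2. Gbp2 and Ifit3b in Foxk2 overexpression, Pes1, Mir194-1 and Snord73a in Foxk1 knockdown and mt-Tk in Foxk2 knockdown each lost the call without some single library. The causes were not tested.

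With the replicate block, changed genes numbered 7335 in the labelled Foxk1 overexpression, 5350 in Foxk1 knockdown, and 6827 and 4960 in those of Foxk2. Same-numbered libraries correlated at -0.0860 to 0.0330 in their deviations, so the numbers do not pair them. Of Foxk1 libraries, 2 of 3 numbers in knockdown and 0 of 3 in the labelled overexpression correlated best with their own number.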

Other observations

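Some genes changed in all 4 comparisons, higher in both overexpressions, the Foxk1 one by label, and lower in both knockdowns. They number 723 of 15981 tested, against 21.5 if the 4 sets of calls were independent, and the following were chosen after their values were seen. Values are in the order labelled Foxk1 overexpression, Foxk1 knockdown, Foxk2 overexpression, Foxk2 knockdown. They include Ak4 (1.69, -2.44, 2.17 and -1.23), Cox7a1 (1.22, -2.20, 2.30 and -1.204) and Cyp2ab1 (1.11, -2.64, 2.02 and -1.27). Lists with 50% or more of their members here gave 12 of 22 cholesterol synthesis genes, 10 of 20 fatty acid oxidation genes, 9 of 17 glycolysis enzymes, 5 of 8 pentose phosphate pathway genes, 7 of 13 pyruvate dehydrogenase regulation genes and 29 of 54 nuclear-encoded respiratory chain genes.

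The reverse, lower in both overexpressions and higher in both knockdowns, was seen in 1116 genes, against 30.6 if independent. Among them were Itgbl1 (-3.48, 1.48, -1.67 and 1.69), Dcn (-2.73, 1.45, -2.14 and 2.11) and Thbs1 (-1.70, 1.89, -2.50 and 1.44). By the same share these hold 24 of 34 extracellular matrix genes, 18 of 22 fibroblast and preadipocyte markers and 7 of 13 myofibroblast and contractile genes. No list was tested for enrichment among them.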
